A study of Mus musculus with 16 samples.

How the data were processed

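The series holds 16 ATAC-seq libraries of mouse HSCs made with the Omni-ATAC protocol from 10000 sorted cells each. Young and old donors were sampled before transplantation, and 1000 of their HSCs were transplanted with 300000 helper cells into 5 lethally irradiated young recipients, whose marrow was pooled 3 months later. The series design pairs the pre and post libraries of a donor pool, so libraries of the same age and number were treated as pairs. The labels do not say whether post HSCs were sorted on a donor marker, so HSCs of the recipients or of the helper marrow cannot be excluded there, and every post value carries this limit. The labels do not say that a number links an old to a young library, and no such link was assumed in the main tests. The labels give a transposition day for each library: day 1 held old pre 1 and 2, day 2 old pre 3 and 4 and young pre 1 to 3, day 3 young pre 4, day 4 old post 1 and 2, day 5 old post 3 and young post 1 and 2, and day 6 old post 4 and young post 3 and 4. Stage is thus fully confounded with day, and days 2, 5 and 6 hold both ages.

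Per the submitters' processing notes, reads were inspected with FastQC and MultiQC, trimmed with Trim Galore and cutadapt, and peaks were called with Genrich on build mm10, with ChIPseeker and featureCounts among the other tools named. The aligner, the versions and the settings are not given in the sources used here. The deposited files are narrowPeak lists with no header, called separately for each library. Column 7 of each deposited list is a score, the area under the caller's significance curve of a peak, with a smallest value of about 200 in every file. Column 5 of the deposited lists is also a score, 1000 times the area per base and capped at 1000, which was checked on every peak. Columns 8 and 9 of the deposited lists are the -log10 p and -log10 q of the peak summit in that library (neg_log10_p). None of these values is normalised between libraries, so only the presence of a peak was compared. Peak numbers ranged from 5711 to 32557 per library and totalled 387029, of which 393 (0.102%) on unplaced scaffolds were left out. No read counts per library were used, so no counting interval is given, and a region without a peak was read as not called, not as closed.

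Peaks on standard chromosomes were merged wherever they overlapped by at least 1 bp in any library, and regions called in at least 2 libraries were kept (33773, median width 830 bp). The RefSeq gene table of GRCm38 holds gene spans without strand, so a gene end is within 1 kb of either end of a gene, in place of a promoter. Of the regions, 32.9% were at gene ends, 39.2% within genes, 24.4% outside genes and 3.50% beyond 100 kb from any of 21627 protein-coding genes. Genome sequence was not used, so the motif scores and the matching on GC content that had been planned were not run, and matching on location class stood in for the latter. Of the 521 genes of 23 fixed lists, 518 matched the gene table.

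For single regions, the number of calls in each group was compared by an exact conditional test, two-sided, in which each library was weighted by its log odds of a call, estimated by conditional maximum likelihood over all regions (a Rasch model). For old against young with both stages pooled, it counts the pre and post libraries of a donor as independent. P values were adjusted by Benjamini and Hochberg over regions called in 4 to 12 of 16 libraries, or 3 to 5 of 8, at a threshold of 0.05. With 4 against 4 libraries the main result was the number of all-or-none regions, called in 4 of 4 libraries of a group and 0 of 4 of the other. Leaving out a library loosens this rule, so the count can then only stay or rise. Each gene list was scored per library as the mean presence of its regions minus the presence expected in that library among regions called in as many of the 16 libraries, in percentage points. Per list these scores sum to 0 over the 16 libraries, so a high score in a group forces lower ones elsewhere. Contrasts that share a group are thus not independent, and a score of 0 is no baseline. List scores were tested with limma 3.58.1 in R 4.3.3, with donor as a random block and adjustment over the 23 lists within each contrast. Exact permutation p values, which cannot go below 0.0286 for 4 against 4, 0.125 for 4 pairs and 0.0078 for 8 pairs, were computed beside them. Peak number, peak width, the share at gene ends, similarity between libraries, the persistence of age differences and the interaction were tested by exact permutation, two-sided, with sign flips within donors for post against pre. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

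Regions were named by a fixed rule: for each comparison of 8 with 8 libraries, the 12 regions per direction with the smallest p among those past the adjusted threshold, a single region per gene. The result of 1 gene that the rule names is not reported here. For each comparison of 4 with 4, the rule takes the 5 all-or-none regions per direction with the highest mean percentile of peak area. It also takes any list gene with an all-or-none region or a region past the threshold, and the members with the largest change in each list past its threshold. The comparisons, tests, lists, naming rule and most alternatives were chosen before the data were examined. Chosen after seeing the data were leaving out the 3 shortest lists (old pre 4, young pre 4 and old post 4), the imprinted gene list, the scan of windows, the relations of a stretch on chromosome 8 with the list scores, the raw calls of 2 lists, the regrouping of whole donors for the test of persistence and the scores of location classes.

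Alternatives were equal-length lists (the 5687 peaks of the shortest list, or the 14008 of the third shortest without the 2 shorter libraries), the top 75% of peaks, summit windows of 250 bp either side, at least 50% overlap, at least 3 libraries, genes within 20 kb, tests without weights, limma, paired and unpaired fits, transposition day, and leaving out each library. The tests were checked on simulated data with the observed list lengths and 200 changed regions per run. At a log odds shift of 4 the region test recovered at most 0.5% of them. At a list shift of 1 on the log odds scale 15% of 20 simulated lists were called, and at 2, 65%. Presence beyond list length correlated between the pre and post libraries of a donor with r from -0.180 to 0.0526, so the pairing could not be checked from the values.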

Results

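Chromatin accessibility was measured by ATAC-seq, which marks open DNA by transposase insertion, in sorted haematopoietic stem cells (HSCs) of young and old male mice before transplantation and in HSCs recovered from the bone marrow of young recipients 3 months after it. There were 4 libraries in each of 4 groups: young before (young pre), old before (old pre), young after (young post) and old after (old post). Each young replicate pooled 3 to 4 donors aged 8 to 12 weeks, and each old replicate was 1 donor aged 24 months. By the series design, the libraries before and after transplantation with the same age and number go back to the same donors. The labels do not say whether HSCs were sorted on a donor marker after transplantation, so HSCs of the recipients or helper cells cannot be excluded from the post libraries. Each library was deposited as its own peak list, so the value compared was whether a region was called open in a library. The lists held 28298, 23044, 21346 and 9614 peaks in young pre 1 to 4, and 27302, 30520, 17299 and 5687 in old pre 1 to 4. After transplantation they held 32530, 30784, 31409 and 32007 peaks in young post 1 to 4, and 23287, 28498, 31003 and 14008 in old post 1 to 4. Reads per library were not used here, and the depth of sequencing behind each list is unknown. The lists merged into 33773 regions called in at least 2 libraries, of which 5262 were called in all 16. Positions are 1-based on mouse build mm10 (GRCm38), and each region was named by the nearest protein-coding gene within 100 kb. In what follows, list scores are in percentage points of regions called beyond what the length of each library's peak list gives, with the standard error (SE) of limma's fit. They are relative: the scores of a list balance out over the 16 libraries, so a high score in a group lowers those of others. In old pre 4 and young pre 4, the shortest lists, most scores lie close to the expected value, yet the fit counts every library equally.

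**Figure D1:**
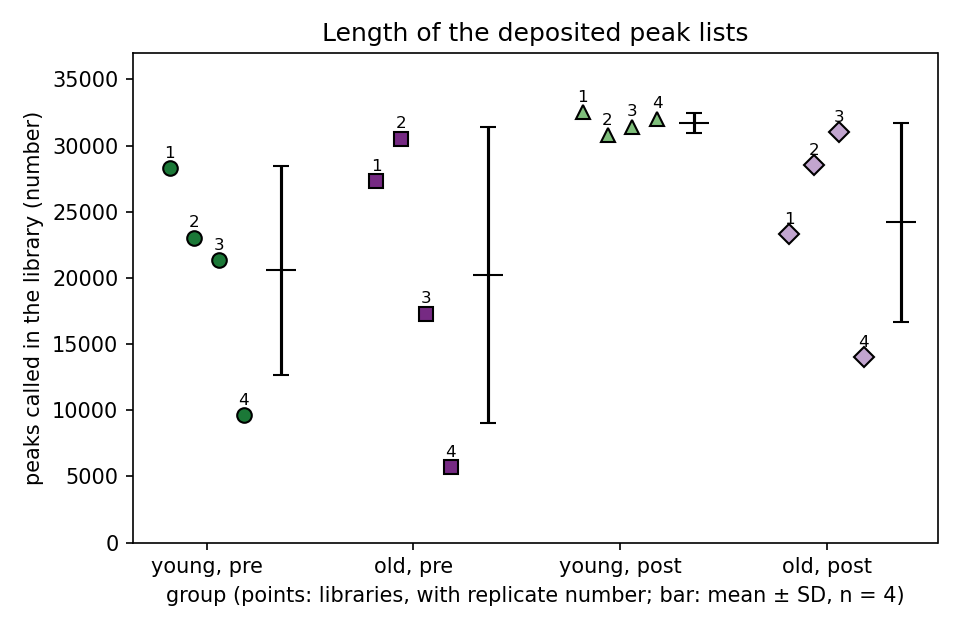
Number of peaks on standard chromosomes in each library (points, n = 4 per group) with the group mean and SD. Young post libraries held 30784 to 32530 peaks, and old pre libraries held 5687 to 30520.

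The comparison of old with young HSCs before transplantation asked which open regions differed with age in freshly isolated cells. Regions at genes reported as higher in old HSCs were called more in old than in young donors, by 17.0 ± 2.63 points (SE, limma adjusted p = 3.3e-05, n = 4 per group). The mean score of this ageing list was -4.95 ± 1.28 (SD) in young pre and 12.1 ± 7.04 in old pre, and 36 of its 39 genes with a region scored higher in old, with 0 lower. Aldh1a1, a retinaldehyde dehydrogenase, was called 6 of 8 possible times in old pre and 1 of 8 in young pre, a difference of 70.2 points. The membrane protein gene Tm4sf1 differed by 68.2 points, the oxysterol receptor gene Gpr183 by 52.5, the Hippo pathway coactivator gene Wwtr1 by 44.1 and the oncostatin M receptor gene Osmr by 40.8. The lymphoid priming list scored lower in old by -6.02 ± 1.96 points (limma adjusted p = 0.0437), and 11 of its 15 genes were lower and 4 higher. Its largest differences were -35.7 points at Satb1, a chromatin organiser of lymphoid cells, -30.8 at the E protein gene Tcf3 and -21.4 at Notch1, against 19.5 at the B-lineage gene Ebf1. The list of AP-1 and immediate early genes also scored lower in old, by -7.28 ± 2.39 points (adjusted p = 0.0437), and was lower at 13 and higher at 6 of its 23 genes. Megakaryocyte and platelet genes, which share 4 genes with the ageing list, differed by 2.60 ± 2.05 points (adjusted p = 0.488). The ageing genes reported as lower in old differed by -5.16 ± 2.10 points (adjusted p = 0.129), and HSC identity genes by 3.65 ± 1.80 (adjusted p = 0.248).

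Old pre 1 and 2 were transposed on a day that held no young library, and scored 20.2 and 15.6 on the ageing list. On day 2, which held both ages, old pre 3 and 4 scored 7.55 and 4.97, and young pre 1 to 3 scored -6.07, -3.28 and -4.62. Of the 103 ageing regions not called in every library, old pre 4 called 6 and young pre 4 called 3. Of 50 such regions of the AP-1 list they called 1 and 5, so scores in these short lists had little room to vary. With transposition day as a covariate the ageing list differed by 10.9 ± 2.36 points (adjusted p = 0.0077), and with the libraries of shared days alone by 6.88 ± 2.83 (adjusted p = 0.350), within a range of 7.6e-06 to 0.350 over its alternatives. These 2 values rest on the same day 2 libraries, and differ in how expected presence and the spread were estimated. Both other lists missed the threshold with the day covariate, at -3.31 points for lymphoid priming (adjusted p = 0.709, range 0.0177 to 0.888) and -7.14 for AP-1 genes (adjusted p = 0.0778, range 0.0043 to 0.557). The lymphoid call was lost without any 1 young library, before or after transplantation, and without old pre 1 or old pre 2 (-6.32 to -4.10 points, adjusted p = 0.0566 to 0.308). It passed in 12 of 31 alternatives. The AP-1 call was lost without young pre 1, 2 or 3, old pre 1, 2 or 4, any 1 young post library, old post 1 or old post 4 (-7.53 to -5.27 points, adjusted p = 0.0560 to 0.237), was -2.91 points with lists shortened to the third shortest (adjusted p = 0.557), and passed in 9 of 31. The lymphoid list scored 13.6 points higher in old when each list was shortened to the shortest (adjusted p = 0.278), 12.8 lower with the third shortest (adjusted p = 0.0376) and 2.99 lower on shared days (adjusted p = 0.888). An exact permutation test of 4 against 4 cannot go below p = 0.0286, and it gave adjusted p = 0.329 as the smallest over the 23 lists.

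**Figure D2:**
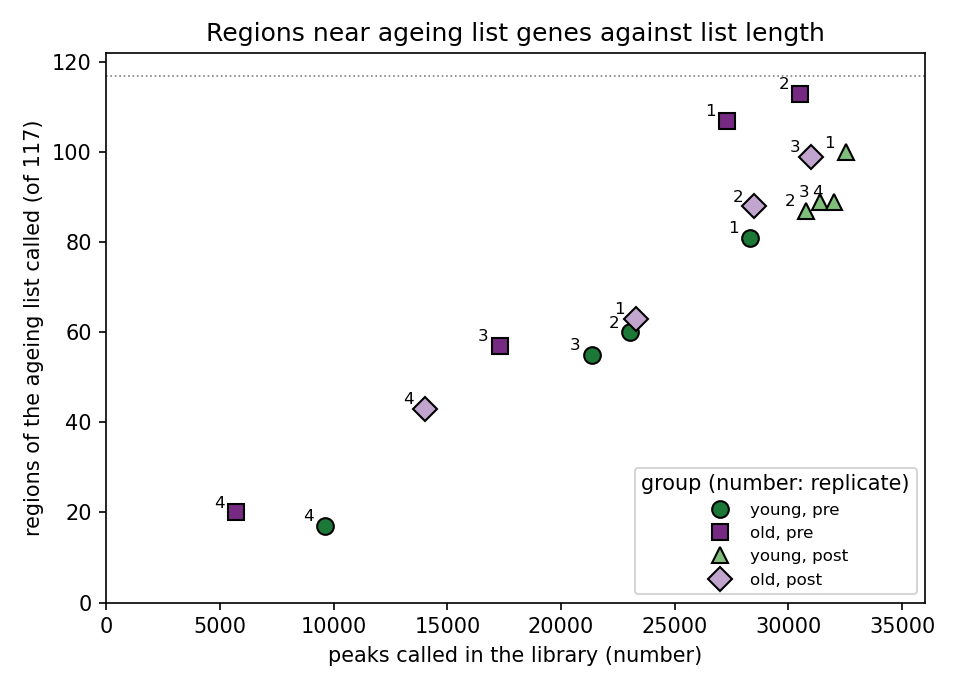
Regions of the ageing list called in each library (of 117) against the number of peaks in that library's list, by group. Old pre 1 and 2 held 107 and 113 of these regions, and young pre 1, whose list was of like length, held 81.

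Across single regions, 0 of 9407 tested passed the depth-weighted exact test in either direction before transplantation. At an unadjusted p under 0.05 there were 215, and limma called 0. Fisher's exact test without weights also called 0, but its smallest p here was 0.143, so it could call none. No region was called in 4 of 4 libraries of 1 age and 0 of 4 of the other. With the 3 shortest lists left out the all-or-none count was 214, of which 127 were called in old alone and 87 in young alone. Leaving out old pre 4, the shortest list, gave 127 such regions, leaving out young pre 4 gave 87 and leaving out old pre 2 gave 1. With fewer libraries this count can only stay or rise, so a rise alone shows nothing about age. Adjusted over the list alone, regions at the immediate early genes Klf6 and Maff passed, 2 in all and both lower in old, against 0 over all regions. Single regions of the stromal gene Bglap and of E2f1 also passed, adjusted over the list alone, both lower in old, against 0 over all regions. In simulated data the test recovered 0% of regions opened in old and 3% of those opened in young at a log odds shift of 8.

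The same comparison after transplantation asked whether age differences were present once both ages had spent 3 months in young recipients. Regions near Srd5a1, which encodes a steroid 5-alpha-reductase, and Nav2, a neuron navigator gene, were called in 4 of 4 old post and 1 of 4 young post libraries (adjusted p = 2.4e-04 each, exact test). In all, 24 of 5163 regions passed the depth-weighted test and all were old-higher, among them regions of Kcnn2, Wars2 and Gabrb1 at 3 of 4 against 0 of 4. In the other direction, 513 regions were called in all 4 young post and no old post library, and none the reverse. They were led by Actb, the cytoskeletal actin gene, the collagen hydroxylase gene P4ha2, Plekha2, the transporter gene Abcc4 and B4galnt2. They included regions of the list genes Msi2, Fli1, Mllt3, Flt3, Cxcr4, Cdkn1b and Irf8.

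The direction of these counts moved with list length: young post lists averaged 31683 ± 754 peaks (SD, n = 4) and old post lists 24199 ± 7516. With lists shortened to the shortest, the all-or-none count was 22 old-higher and 17 young-higher, and to the third shortest, 43 and 46. The depth-weighted test then called 0 and 0, while limma on the full lists called 101 old-higher and 251 young-higher. Without young post 2, 3 or 4 in turn the depth-weighted count was 0, without old post 1, old post 2 or young post 1 it was 2, and without old post 3 it was 4. The all-or-none count, which can only stay or rise when a library is left out, was 1808 without old post 3 and 799 without young post 2. No list passed after transplantation (0 of 23 by limma, 0 by exact permutation), and the 3 with the smallest adjusted p were ageing genes, cytokine receptors and granulocyte and monocyte genes. The ageing list differed by 7.05 ± 2.63 points (adjusted p = 0.104), with 29 of 39 genes higher in old and 7 lower. Before adjustment for list length, 63, 88, 99 and 43 of its 117 regions were called in old post 1 to 4, and 100, 87, 89 and 89 in young post 1 to 4. The ageing list passed with the day covariate (9.31 points, adjusted p = 0.0197), with lists shortened to the third shortest (15.3 points, adjusted p = 0.0154) and without young post 1 (9.44 points, adjusted p = 0.0230), within a range of 0.0154 to 0.731. In all, 2 lists passed without young post 1 and 2 without old post 4. Adjusted over the list alone, 1 region of the ageing list passed, at Tm4sf1, against 0 over all regions. In simulated data 12% of regions opened in old and 0% of those opened in young were recovered at a log odds shift of 8.

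Pooling both stages, the comparison of 8 old with 8 young libraries called 41 of 15182 regions, 38 of them old-higher and 3 young-higher. The test counts the pre and post libraries of a donor as independent, so its p values may be too small for 4 donors or pools per age. Permuting whole donors, 4 against 4, cannot give p below 0.0286. Regions of Srd5a1 (chromosome 13, 69594598 to 69595642) and Nav2 (chromosome 7, 49321027 to 49321632), both within the gene, were called in 7 of 8 old and 1 of 8 young libraries (adjusted p = 2.5e-04 each). Wars2, encoding a mitochondrial tryptophan tRNA synthetase, the potassium channel gene Kcnn2 and a region on chromosome 2 at 54198134 were called in 6 of 8 old and 0 of 8 young libraries (adjusted p = 0.0014). The ageing list gene Tm4sf1 (chromosome 3, 57294551 to 57295637, within the gene) was called in 6 of 8 old and 1 of 8 young libraries (adjusted p = 0.0107). The same counts were seen near Gabrb1, a GABA receptor subunit gene, Gm3248, the adhesion receptor gene Adgrg2, the neurofascin gene Nfasc, and regions more than 100 kb from a gene on chromosome 6 at 3182749 and chromosome 9 at 30137667. The young-higher regions lay near Plekha2, Mctp1 and Kctd20, each called in 0 of 8 old and 7 of 8 young libraries (adjusted p = 0.0353).

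**Figure D3:**
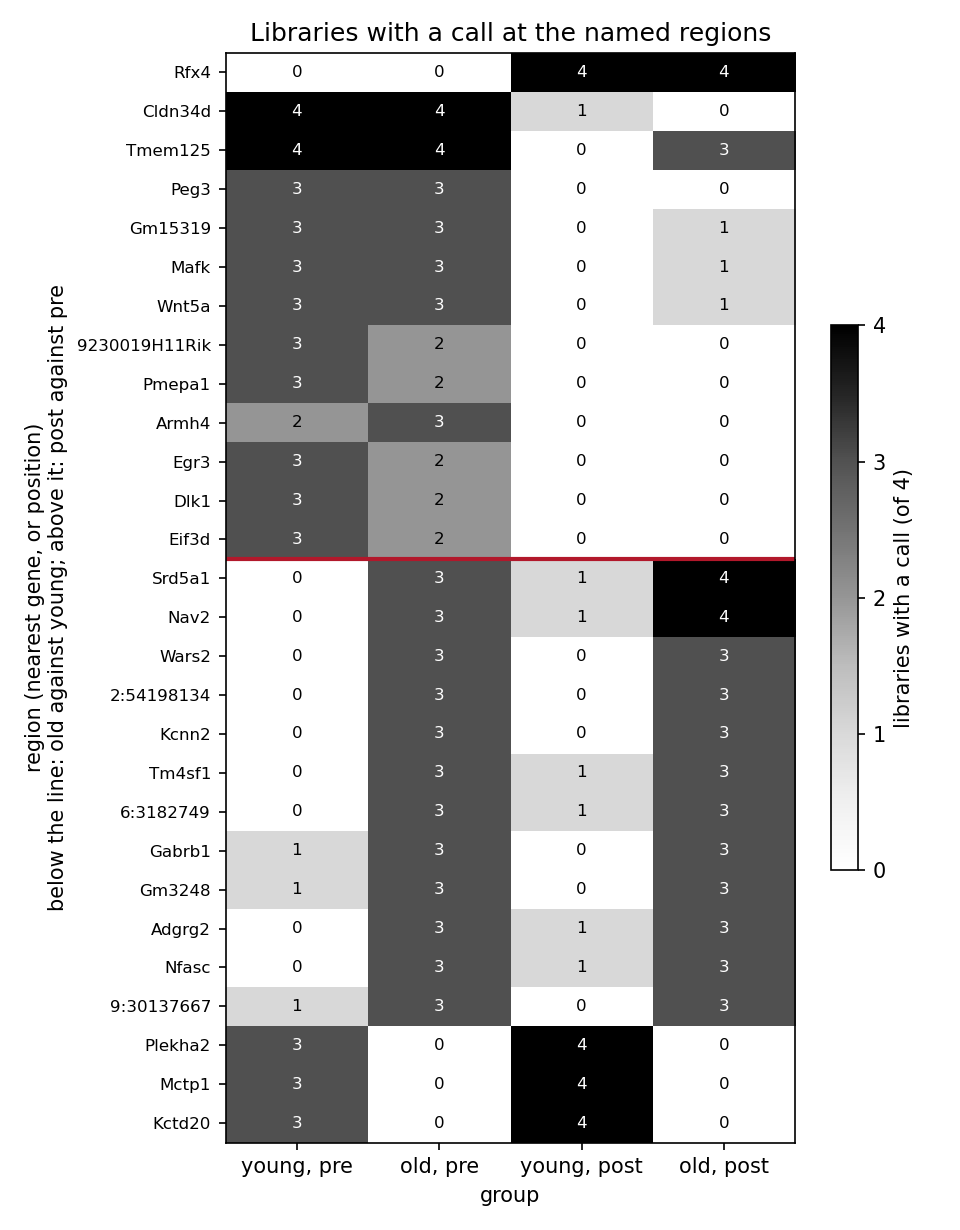
Number of libraries (colour, of 4) with a call in each group (columns) for each region named by rule (lines), post against pre above the dividing line and old against young below it. The Rfx4 region was called in 8 post and 0 pre libraries, and the Nav2 region in 7 old and 1 young library.

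At an unadjusted p under 0.05 there were 693 regions, and the other tests differed in number and direction. Fisher's exact test called 0, with a smallest p of 0.0014, at which a few regions cannot pass the adjustment. Limma called 116 old-higher and 254 young-higher. With old and young libraries of the same number as pairs the count was 2, on shared transposition days 7, and with lists shortened to the third shortest 10, all old-higher. The count was 2 without old pre 3, 13 without old pre 1, 8 without young post 1, 7 without young post 3, 7 without young post 4 and 65 without old post 2. Adjusted over the list alone, 2 regions of the ageing list passed, at Aldh1a1 and Tm4sf1, against 1 over all regions. A region of the chromatin regulator Ezh1 passed, adjusted over the list alone, against 0 over all regions. Regions beyond 100 kb from a gene made up 6 of the 38 old-higher regions and 4.58% of the others tested (Fisher's exact p = 0.0073, adjusted p = 0.117). As a class, chosen after the values were seen, such regions scored 8.45 points higher in old before transplantation and 3.29 after (exact p = 0.0286 and 0.0571, respectively). In simulated data 76% of regions opened in old and 31% of those opened in young were recovered at a log odds shift of 8.

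Over both stages the ageing list scored 12.0 ± 1.86 points higher in old (limma adjusted p = 3.4e-05), with 33 of 39 genes higher and 3 lower, and by 6.23 ± 1.95 on the shared transposition days (adjusted p = 0.163, range 3.6e-06 to 0.163). Lymphoid priming genes scored lower by -5.41 ± 1.38 points (adjusted p = 0.0082), with 13 of 15 genes lower, among them Il2rg, the shared cytokine receptor gamma chain, at -21.4 points, the B-cell adaptor gene Blnk at -21.0 and Satb1 at -19.2. This list missed the threshold without old pre 1 (-4.73 points, adjusted p = 0.0540), with the day covariate (-3.74, 0.259), on shared days (-2.99, 0.422) and at gene ends alone (-7.19, 0.219), and its difference was 0.465 points with lists shortened to the shortest (range of adjusted p 0.0026 to 0.954). The smallest adjusted p by exact permutation over the 23 lists was 0.131. Without old pre 3, 4 lists passed (1 higher and 3 lower in old). With all libraries the other 21 lists did not pass, at adjusted p of 0.107 or more, among them 0.149 for DNA damage response, 0.133 for autophagy and lysosome, cytokine receptor, and endothelial and stromal genes, and 0.258 for TGF-beta and BMP genes.

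Regions selected by their calls before transplantation were compared between the ages on the post libraries of the same donors. None of the 9407 regions tested had passed between ages before transplantation, so the selected regions are not established age differences. Among 127 regions called in at least 3 more old than young pre libraries, the old minus young difference after transplantation was 26.5 points, and among 88 regions selected the other way it was -6.40. The sets differed by 32.9 points (exact permutation of age over the post libraries, p = 0.0286, the smallest that 4 against 4 can give). With whole donors regrouped and regions selected again, 2 of 35 groupings held enough regions in both directions, too few for a test. Groupings that mixed the ages selected up to 6731 regions in a single direction. The one that exchanged old 4 for young 4 gave 20.6 points, so age was not separated from differences between single donors. A permutation of donor age over all regions did not show the change with transplantation to differ between the ages (mean squared difference 643.8, exact p = 0.114). Among the lists, 0 of 23 interactions passed (limma, and 0 by exact permutation), with -9.96 ± 3.72 points for the ageing list (adjusted p = 0.132) and 10.2 ± 3.37 for AP-1 genes (adjusted p = 0.132). Without young pre 4, 1 interaction passed.

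The comparison of post with pre libraries over both ages asked which regions differed between HSCs before transplantation and those recovered after it. A region within Rfx4, a winged-helix transcription factor gene (chromosome 10, 84897754 to 84898897), was called in 8 of 8 post and 0 of 8 pre libraries (adjusted p = 0.0125, exact test). Of 61 regions called, it was the only post-higher region, and 60 were pre-higher. The claudin family gene Cldn34d (chromosome X, 76598672 to 76599180, within the gene) was called in 8 of 8 pre and 1 of 8 post libraries (adjusted p = 8.5e-13), and a region 2962 bp from Tmem125 (chromosome 4, 118547015 to 118548781) in 8 and 3 (adjusted p = 1.1e-09). P values this small hang on calls in the shortest lists. The model's relative odds of a call were 1.1e-05 in old pre 4 and 6.5e-04 in young pre 4, against 45.1 in young post 1. Without these weights, Fisher's exact test called no region, but its smallest p was 1.6e-04, at which a few regions cannot pass the adjustment. A region of the imprinted gene Peg3 (chromosome 7, 6728180 to 6729042) was called in 6 of 8 pre and 0 of 8 post libraries (adjusted p = 1.9e-05). Regions of Wnt5a, a secreted Wnt ligand, of the small Maf gene Mafk and of Gm15319 were called in 6 pre and 1 post library (adjusted p = 2.3e-04). Regions called in 5 pre and 0 post libraries (adjusted p = 9.7e-04) lay near the immediate early gene Egr3, the imprinted gene Dlk1, the translation factor gene Eif3d, Pmepa1, an inhibitor of TGF-beta signalling, Armh4 and 9230019H11Rik.

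The AP-1 and immediate early list fell by 7.67 ± 1.69 points after transplantation (limma adjusted p = 0.0034), with 12 of 23 genes lower and 7 higher. By age the difference was -12.8 ± 2.38 points in young and -2.58 ± 2.38 in old donors (adjusted p = 4.7e-04 and 0.558, respectively). Adjusted over the list alone, 5 of its regions passed, at Egr3, Ier3 and Nr4a2 and all pre-higher, against 2 over all regions. The AP-1 call was lost with lists shortened to the shortest (-2.98 points, adjusted p = 0.522) or the third shortest (-2.55, 0.310) and at gene ends alone (-4.86, 0.0742), within a range of 1.5e-04 to 0.522. By exact permutation neither it nor the ageing list passed (adjusted p = 0.144 each). The ageing list fell by 7.11 ± 1.86 points (adjusted p = 0.0103), with 22 of 39 genes lower and 14 higher. By age the difference was -12.1 ± 2.63 points in old and -2.13 ± 2.63 in young donors (adjusted p = 0.0030 and 0.820, respectively). This call was lost with donor as a fixed block (adjusted p = 0.0818), with the top 75% of peaks (-6.28 points, 0.0653), with lists shortened to the third shortest (-6.41, 0.139), away from gene ends (-6.29, 0.0847), without old pre 1 (-4.50 points, adjusted p = 0.0654), without old pre 2 (-5.13, adjusted p = 0.106) and without young pre 4 (-6.66, adjusted p = 0.0527), within a range of 9.2e-04 to 0.139. Without old post 1, 8 lists passed (5 higher and 3 lower after transplantation), and without old post 2, 4 passed (1 and 3). With all libraries, lists that did not pass differed by -5.83 ± 2.48 points for Hox genes (adjusted p = 0.106), 4.02 ± 1.56 for NF-kB and inflammation (0.0981), 3.11 ± 1.72 for erythroid genes (0.192), 2.84 ± 1.42 for the cell cycle (0.148), 2.29 ± 1.45 for the interferon response (0.268) and -2.80 ± 1.27 for chromatin regulators (0.124). For T and NK cell markers the difference was -2.66 ± 1.88 points (adjusted p = 0.326), for mature B cell markers 1.68 ± 2.43 (0.599), for quiescence and CDK inhibitors -1.41 ± 1.61 (0.588), for glycolysis and hypoxia -0.402 ± 1.30 (0.796) and for niche adhesion and homing 0.346 ± 1.59 (0.830).

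**Figure D4:**
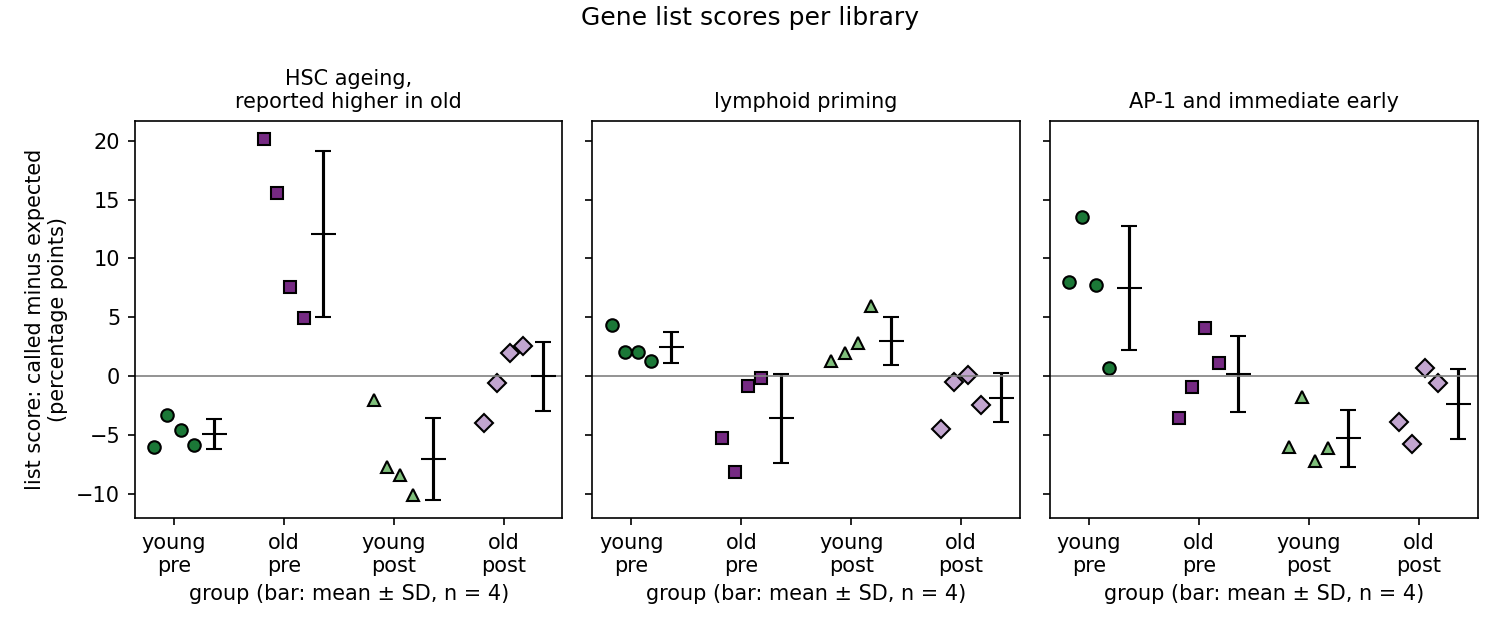
Scores of the ageing, lymphoid priming, and AP-1 and immediate early lists in each library (points) with group means and SD (bars, n = 4), in percentage points beyond the presence that list length gives. On the ageing list, old pre averaged 12.1 and young pre -4.95.

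Of 15182 regions tested, 853 had an unadjusted p under 0.05. Fisher's exact test called 0, with a smallest p of 1.6e-04, at which a few regions cannot pass the adjustment. Limma called 0 post-higher and 12 pre-higher. The direction of the calls depended on list length: with lists shortened to the third shortest there were 37 post-higher and 9 pre-higher regions, and with the shortest there were 0. In the paired test within donors the count was 35, and it was 34 without young pre 1 and 34 without old pre 3. In simulated data 13% of regions opened after transplantation and 81% of those opened before it were recovered at a log odds shift of 8. Every post library came from another transposition day than every pre library, so the day and the stage cannot be told apart.

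Within young donors, the score of the AP-1 and immediate early list, in points beyond what list length gives, fell by 12.8 ± 2.38 points after transplantation (limma adjusted p = 4.7e-04), from a mean of 7.47 in young pre to -5.28 in young post, with 14 of 23 genes lower and 5 higher. Before this adjustment, 73, 68, 62 and 37 of its 82 regions were called in young pre 1 to 4, and 69, 69, 66 and 68 in young post 1 to 4. The nuclear receptor gene Nr4a2 differed by -68.8 points, Egr3 by -73.1, the small Maf gene Maff by -35.3 and the zinc finger gene Klf6 by -16.5, against 15.0 at Jun. Single regions of Nr4a2, Klf6, Egr3 and Maff were called in 3 of 4 pre and 0 of 4 post libraries (adjusted p = 0.0017 each). Adjusted over the list alone, 6 AP-1 regions passed, against 5 over all regions, and 1 region of the megakaryocyte factor Nfe2 passed against 0. Granulocyte and monocyte genes scored 7.76 ± 2.21 points higher after transplantation (adjusted p = 0.0220), with 11 of 17 genes higher, among them the lysozyme gene Lyz2 at 35.7 points and the alarmin gene S100a9 at 26.8, and 5 lower, among them F13a1 at -29.9.

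With lists shortened to the third shortest the AP-1 difference was -2.62 ± 2.60 points (adjusted p = 0.538) and the granulocyte difference turned to -1.34 ± 3.66 (adjusted p = 0.838), within ranges of 1.4e-05 to 0.538 and 0.0043 to 0.838. With the shortest, the granulocyte difference was -8.82 ± 5.62 points (adjusted p = 0.503), and its call passed in 19 of 29 alternatives. It was also lost with the top 75% of peaks (6.87 points, adjusted p = 0.0738), in regions of at least 3 libraries (6.09, 0.0865), at gene ends alone (10.9, 0.400), away from them (7.21, 0.0827), and without young pre 1 (5.52 points, adjusted p = 0.261), young pre 2 (7.01, 0.0774), young post 2 (7.66, 0.0642) or young post 3 (6.75, 0.130). By exact permutation of 4 pairs, which cannot go below p = 0.125, the smallest adjusted p was 0.359.

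Called after transplantation in all 4 young libraries and before it in none were 2409 regions, and the reverse held for 1 region, at Tmem125. Every young post list was also longer than every young pre list, so these counts are not apart from list length. The leading post-only regions lay at Aldh1a1 (chromosome 19, 20600794 to 20602417), Odf2l, Mfsd12, the lipid raft gene Rftn1 and the Toll-like receptor gene Tlr6. They included regions of the stem cell factors Gata2, Meis1 and Erg and of the myeloid genes Cebpa, Csf1r and Lyz2. Beyond list length, HSC identity genes did not rise in young donors (-1.27 ± 1.79 points, limma adjusted p = 0.862, 12 genes higher and 12 lower). The glycolysis and hypoxia list, which holds Meis1, scored 0.936 points with it and 2.39 without it, so the regions of Meis1 together scored lower. By the depth-weighted test 66 of 8867 regions passed, all pre-higher, with 302 at an unadjusted p under 0.05. Limma called 251 post-higher and 75 pre-higher. Fisher's exact test called 0, but with 4 against 4 it cannot go below p = 0.0286, so this 0 tests nothing. With lists shortened to the shortest the all-or-none counts were 74 post-only and 26 pre-only, and to the third shortest 259 and 145. The depth-weighted count was 4 in the paired test, 6 without young pre 1, and 2 without young pre 2 or young pre 3. The all-or-none count, which can only stay or rise with fewer libraries, was 5751 without young pre 1. In simulated data 0% of regions opened after and 35.5% of those opened before transplantation were recovered at a log odds shift of 8.

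Within old donors, the ageing list fell by 12.1 ± 2.63 points (limma adjusted p = 0.0030), from 12.1 in old pre to -0.0289 in old post, with 28 of 39 genes lower and 8 higher. These scores are relative to the mean over all libraries, so a score near 0 does not mark a baseline. Scores in pairs 1 to 4 were 20.2, 15.6, 7.55 and 4.97 before and -3.97, -0.608, 1.94 and 2.51 after. The fall was largest in pairs 1 and 2, whose pre libraries came from a day without young ones. Before adjustment, 107, 113, 57 and 20 of 117 regions were called in old pre 1 to 4, and 63, 88, 99 and 43 in old post 1 to 4. Whether HSCs of the young recipients were part of the old post libraries was not tested, and the labels do not settle it. This call was lost with lists shortened to the third shortest (-12.6 points, adjusted p = 0.0656) and away from gene ends (-11.1, 0.0525), within a range of 2.6e-04 to 0.0656. The NAD-consuming enzyme gene Cd38 differed by -66.3 points, Gpr183 by -53.3, Osmr by -42.5, the BMP receptor gene Bmpr1a by -37.3 and the clusterin gene Clu by -24.5. Adjusted over the list alone, 3 ageing regions passed, at Clu, Gpr183 and Osmr and all pre-higher, against 0 over all regions. HSC identity genes fell by 6.13 ± 1.79 points (adjusted p = 0.0274), with 18 of 26 genes lower and 6 higher, among them the transcription factor genes Mecom at -16.8 points, Meis1 at -10.6 and Fli1 at -10.0, and Fgd5 at -12.8. The HSC identity call was lost with donor as a fixed block (adjusted p = 0.0766), without old pre 1 (-4.91 points, adjusted p = 0.109), old pre 2 (-4.75, 0.194), old pre 3 (-5.83, 0.0536) or young post 3 (-6.03, 0.0529), with lists shortened to the shortest (-10.1, 0.445) or the third shortest (-9.23, 0.0877), with the top 75% of peaks (-6.52, 0.156), at gene ends alone (-2.12, 0.783) and away from them (-6.69, 0.0525), within a range of 0.0077 to 0.783. It passed in 19 of 29 alternatives. Without old post 1, 4 lists passed (2 higher and 2 lower after transplantation). By exact permutation of 4 pairs the smallest adjusted p over the lists was 0.575. Single regions of Osmr, as a cytokine receptor gene, and of Epas1, a hypoxia-inducible factor, passed adjusted over the list alone, both pre-higher, against 0 over all regions.

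Cldn34d was the only region of 10384 past the adjusted threshold in old donors, called in 4 of 4 pre and 0 of 4 post libraries (adjusted p = 1.6e-05), with 506 at an unadjusted p under 0.05. Limma called 0, and so did Fisher's exact test, which with 4 against 4 cannot go below p = 0.0286 and so tests nothing here. Regions of Rfx4, the kinase gene Lrrk1 and the ubiquitin ligase gene Cblb were called in all 4 old post and no old pre library. The all-or-none count of 4 (3 post-only, 1 pre-only) was 433 without the 3 shortest lists (382 and 51), 31 with lists shortened to the shortest (19 and 12) and 329 to the third shortest (171 and 158). The all-or-none count was 383 without old post 4, 54 without old pre 4, 12 without old pre 2 and 7 without old pre 1, but can only stay or rise with fewer libraries. The depth-weighted count was 4 without old pre 3, 2 without old pre 2, 0 without old pre 4 and 51 without the 3 shortest lists. In simulated data 0% of regions opened in either direction were recovered at a log odds shift of 8.

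Libraries themselves differed in size: post lists held 7552 more peaks than pre lists of the same donors, on average, in 6 of 8 pairs (paired exact permutation p = 0.0391, adjusted p = 0.214 over 15 tests). Peaks at gene ends made up 47.2 ± 11.5% (SD, n = 8) of pre lists and 38.2 ± 6.11% of post lists (exact p = 0.0469, adjusted p = 0.214), and lists shortened to the shortest differed by -0.165 points (exact p = 0.891). Both stage differences missed the threshold without any 1 young pair, old pair 3 or old pair 4 (exact p = 0.0625 to 0.0938). Old minus young differences in peak number missed the threshold of the permutation test before transplantation (-373.5, exact p = 0.971) and after it (-7484, exact p = 0.0571), and the latter was -9752 without old post 3 (exact p = 0.0286). Median peak widths were 683 ± 76.0, 650 ± 86.5, 697 ± 11 and 660 ± 41.6 bp (SD, n = 4) in young pre, old pre, young post and old post, with no difference past the threshold on the full lists. The old minus young width after transplantation, -37.5 bp (exact p = 0.0571), was -287.75 bp with lists shortened to the shortest and -46.7 bp without old post 3 (exact p = 0.0286 each). Shortening keeps the peaks of largest area, so longer lists keep wider ones, with medians of 880 bp in old post 4 and 1595 in young post 4. The value of -287.75 bp therefore still depends on list length. With presence adjusted for list length, the mean correlation was higher within than between ages before transplantation (by 0.132, exact p = 0.0286) and after it (by 0.117, exact p = 0.0286, the smallest possible). After transplantation, pairs of young post libraries correlated at 0.0774 to 0.185 and pairs of old post libraries at -0.0891 to 0.113, so the old ones did not clearly resemble each other. Before it, single pairs weighed on the means, with 0.368 for old pre 1 and 2, of the same day, and -0.369 for young pre 4 and old pre 4. The mean correlation was also higher within than between stages (by 0.0975, exact p = 0.0078, the smallest that 8 pairs can give), and without old pre 2 the value was 0.0604. On the shared transposition days the age values were 0.0150 before (exact p = 0.600) and -0.00263 after (exact p = 0.533), with fewer libraries. The age value after transplantation missed the threshold without young post 1, 3 or 4 (0.108, 0.0869 and 0.104), and the value before it without young pre 4 (0.140), at exact p = 0.0571 each. Without old pre 1 the value before transplantation was 0.0810.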

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

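The tests of explanations in this part and the counts over splits for gene lists were chosen after the results were seen, and the splits for single regions and the screen for single samples were planned. Among 116 groups of 4 samples screened for a single sample far from the other 3, 5 stood out, and chance alone gives about 1 in 20 groups.

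The score of endothelial and stromal markers in young pre 1 was 5.065, far above the other young pre samples, and its cell cycle score of -4.142 was far below them. The interferon response score of old post 1 was -4.905, far below the other old post samples. The NF-kB and inflammation score of old pre 3 was -7.119, far below the other old pre samples. The median peak area of old post 4, the shortest post list, was 465.3, far below the other old post samples.

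The test of whether the change with transplantation differs between old and young donors gave an unadjusted exact p of 0.0286 for 3 of 23 lists, the smallest that 4 against 4 can give, and none passed after adjustment (adjusted p = 0.219). The old minus young difference in change was 10.18 points for AP-1 and immediate early genes, -8.038 for granulocyte and monocyte genes and -5.059 for cytokine receptors, and none passed with limma either (adjusted p = 0.132, 0.132 and 0.285).

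On unplaced scaffolds, which no comparison used, there were 393 peaks, 21 to 37 in each library.

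The ageing list was called more in old than in young donors before transplantation. List length as the whole cause is argued against by equal-length lists, where the difference was 27.70 ± 4.2 points (SE, limma adjusted p = 1.3e-04). With transposition day as a covariate the difference was 10.92 ± 2.36 points (limma adjusted p = 0.0077). On the shared days alone, without old pre 1 and 2 and young pre 4, it fell from 17.0 ± 2.63 to 6.88 ± 2.83 (adjusted p = 0.350). Both fits rest on the same day 2 libraries, old pre 3 and 4 and young pre 1 to 3, and fall on either side of the threshold. They therefore do not settle whether transposition day is the whole cause. Megakaryocytes or platelets in the old samples would raise the markers of that lineage, which differed by 2.603 ± 2.05 points (adjusted p = 0.488), against 17.0 for the ageing list, and 4 of its genes are on both lists. A difference between old and young HSCs, which the design names, stays open as a hypothesis, together with effects of day and of single donors, since each old library was 1 mouse.

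In young donors the AP-1 and immediate early list scored lower after than before transplantation with list length adjusted for, while its raw calls were 37 to 73 of 82 before and 66 to 69 after. List length cannot be told apart from it, since with lists shortened to the third shortest the difference went from -12.8 ± 2.38 to -2.622 ± 2.60 points (limma adjusted p = 0.538, range over the alternatives 1.4e-05 to 0.538), a smaller change with a like spread, while without the 3 shortest lists it was -15.0 ± 2.31. The transposition day cannot be told apart either, since 0 days held libraries of both stages. A change in the cells with transplantation is a candidate explanation that was not tested apart from these, nor were HSCs of the recipients in the post libraries.

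Of the 61 regions called between post and pre libraries, 60 were pre-higher. List length may set this direction: with equal-length lists, 37 calls were post-higher and 9 pre-higher, and in simulated data 13% of regions opened after and 81% of those opened before transplantation were recovered. What stays open is which of the 60 regions reflect the cells, since no biological explanation was tested.

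Counts over other splits of the samples were made for each comparison. For post against pre over both ages, chance could be excluded for the depth-weighted calls (1 of 100 splits gave as many as 61, highest other 60) and for the all-or-none region (1 of 100, real 1, highest other 0). The split with 60 calls differed from the real labels in old pair 4 alone. For old against young over both stages, chance could be excluded for the 41 calls (1 of 35 splits, highest other 2). Every split reaches a count of 0 (35 of 35), so the splits test nothing for the 0 all-or-none regions over both stages (highest other 1), or for the 0 calls (highest other 2) and 0 all-or-none regions (highest other 1068) between ages before transplantation. The split with 1068 parts the 4 longest from the 4 shortest lists, a structure of the samples other than age. After transplantation, chance could not be excluded for the 24 calls (2 of 35 splits, highest other 42) and could be for the 513 all-or-none regions (1 of 35, highest other 186). The real split also comes close to parting long from short lists, since young post held 30784 to 32530 peaks and old post 14008 to 31003, so excluding chance does not show an effect of age. Without old post 3, the longest old post list, the count was 1808, but leaving out a library can only keep or raise it. For post against pre within an age, only 8 splits part all 4 pairs, too few for a share under 5%. Among them, the young counts of 66 calls and 2410 all-or-none regions compare with at most 1 and 53 in the others, and the old counts of 1 and 4 with 0 and 0. In young donors the real split also parts the longer from the shorter lists, since young post held 30784 to 32530 peaks and young pre 9614 to 28298. The 2410 all-or-none regions therefore do not show an effect of stage apart from list length. The paired exact test called 4 regions in young donors. Splits that keep a pair together gave up to 8 calls and 323 all-or-none regions in young and 3 and 2438 in old donors, and the split with 2438 again parts the 4 shortest from the 4 longest lists, a structure of the samples other than stage.

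For the number of lists past the threshold, chance could be excluded for old against young over both stages (2 lists, 1 of 35 splits, highest other 1) and for post against pre over both ages (2 lists, 4 of 100 splits, highest other 2). Chance could not be excluded for old against young before transplantation (3 lists, 2 of 35 splits, highest other 3). With 0 lists after transplantation and 0 for the interaction the splits test nothing (35 of 35 and highest other 1 in both). The 8 splits that part all pairs are too few in young (2 lists, highest other 0) and in old donors (2 lists, highest other 3).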

How the results depend on the processing

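The alternative without the 3 shortest lists and the regrouping of whole donors were chosen after seeing the data, and the others were not. List length limits most of these results: the lists held 5687 to 30520 peaks before and 14008 to 32530 after transplantation, and a region without a peak may be open below the caller's threshold (with equal-length lists, 37 of 46 calls between post and pre were post-higher, against 1 of 61). The test of persistence kept its direction under every alternative run, at 23.7 to 38.0 points, except that regrouping whole donors gave too few groupings for a test. Its exact p stayed at 0.0286, the smallest that 4 against 4 can give, so the p value cannot show how stable it was. The ageing list before transplantation was higher in old under all 31 alternatives, at 6.88 to 38.4 points, past the threshold in 30 by limma and not by exact permutation. Requiring 50% overlap or a summit and requiring a summit -log10 p of at least 5 kept every result they were run on within its direction, threshold side or 1.5 times its count. Motif scores, matching on GC content and selection of regions at 4 of 4 against 0 of 4 libraries for the persistence test were not run or gave no regions. Other than where stated below, the cause of a difference was not tested. Of the 28 regions named for the comparisons of 8 with 8 libraries, 17 of 18 missed the threshold with lists shortened to the third shortest, 12 of 26 with the top 75% of peaks, 3 of 28 with summit windows, 1 of 13 with donor pairs and 13 of 15 with numbers as pairs across ages, and none turned direction.

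With lists shortened to the shortest, regions past the test were 0 for post against pre over both ages (61 with full lists), 0 for old against young over both stages (41), and 0 for the depth-weighted calls of old against young after transplantation (24), post against pre in young (66) and in old (1). All-or-none regions were 48 before (0 with full lists) and 39 after transplantation (513, reversed in direction) between ages, 100 in young (2410) and 31 in old donors (4). The width difference after transplantation was -287.75 bp (exact p = 0.0286), which still depends on list length because longer lists kept wider peaks. The shares at gene ends differed by -1.873 points between ages before transplantation (reversed), -0.1649 between stages and 1.033 between stages in old donors (reversed). Similarity by age before transplantation was 0.04801. Lists past the threshold were 1 between ages before transplantation, 0 between stages in young, 4 in old, 1 over both ages, 1 between ages over both stages and 3 for the interaction. Lymphoid priming reversed to 13.63 points before transplantation (adjusted p = 0.278, range 0.0177 to 0.888) and 0.4655 over both stages (adjusted p = 0.954, range 0.0026 to 0.954), and granulocyte and monocyte genes in young to -8.820 (adjusted p = 0.503, range 0.0043 to 0.838). With lists shortened to the third shortest, the counts of regions were 46 between stages over both ages (reversed in direction), 10 between ages over both stages, 456 and 89 all-or-none between ages before and after transplantation, 404 in young and 329 in old donors, and 0 for the depth-weighted calls after transplantation, in young and in old. Similarity by age before transplantation was 0.2418 (exact p = 0.100, 3 against 3 libraries). Lists past the threshold were 1 between ages after transplantation, 0 between stages in old donors and 2 over both ages (reversed in direction), and granulocyte and monocyte genes reversed to -1.343 points in young.

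With the top 75% of peaks the counts were 39 between stages, 17 between ages, 9 for calls after transplantation, 1 all-or-none and 0 called in old donors, and lists past the threshold were 1 in each of between ages before transplantation, between stages in young, in old and over both ages. With summit windows they were 108 between stages, 164 called in young and 3 in old donors, and 5 lists between ages over both stages. Fisher's exact test without depth weights, whose smallest p cannot pass in 4 against 4 and was 1.6e-04 in 8 against 8, where a few regions cannot pass either, called 0 between stages, 0 between ages over both stages, 0 after transplantation, 0 in young and 0 in old donors. Limma with the replicate block called 12 between stages, 370 between ages over both stages, 352 after transplantation and 326 in young donors, the last 3 with most calls in the other direction than the exact test, and 0 in old donors.

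With donor pairs as the replicate block, the paired exact test called 35 regions between stages and 4 in young donors, and with the number as the block across ages 2 regions between ages over both stages and 0 after transplantation. Without the block, the difference in peak number of 7552 had exact p = 0.0729 and that in the share at gene ends, -8.954 points, exact p = 0.0741. With donor or number as a fixed term, lists past the threshold were 1 between ages before transplantation, 1 between stages in old, 1 over both ages and 1 for the interaction. The replicate block changed no other call of a comparison.

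On the transposition days that hold both ages, 7 regions were called between ages over both stages and 2 after transplantation, all-or-none regions were 3142 before (2 old against 3 young libraries) and 853 after (2 against 4), similarity by age was 0.01495 before and -0.002626 after (reversed), and 0 lists passed before transplantation and 0 over both stages. With day as a covariate, lists past the threshold were 1 between ages before transplantation, 1 after and 1 over both stages. Without the 3 shortest lists, all-or-none regions were 214 between ages before transplantation and 433 in old donors, 51 were called in old donors, and 5 lists passed between stages over both ages and 2 for the interaction. Regions in at least 3 libraries gave 1 list between ages before transplantation and 1 in young donors, matching on location 1 before transplantation, and genes within 20 kb 5 before transplantation and 4 in young donors. Exact permutation in place of limma gave 0 lists between ages before transplantation, 0 in young, 0 in old, 0 between stages and 0 between ages over both stages. Regions away from gene ends gave 1 list in young, 0 in old and 1 between stages, and regions at gene ends 1 between ages over both stages.

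Leaving out each library in turn gave 34 (without young pre 1 or old pre 3) to 71 regions between stages, and 2 (without old pre 3) to 65 (without old post 2) between ages over both stages. All-or-none counts were 0 to 127 (without old pre 4) between ages before transplantation, 533 to 1808 (without old post 3) after it, 2424 to 5751 (without young pre 1) in young and 4 to 383 (without old post 4) in old donors. Such counts can only stay or rise when a library is left out, so their rise says nothing about the result. Depth-weighted calls were 0 (without young post 2, 3 or 4) to 20 after transplantation, 2 (without young pre 2 or 3) to 83 in young and 0 (without old pre 4) to 4 (without old pre 3) in old donors. Peak number differed by -4027 (without young pre 4) to 4465 (without old pre 4) between ages before transplantation, -9752 (without old post 3, exact p = 0.0286) to -4087 after it, and 5432 (without young pair 4) to 9204 between stages. Median width differed by -66.08 to 9.333 (without old pre 4) bp between ages before transplantation, -46.67 (without old post 3, exact p = 0.0286) to -17.00 after it, -2.286 (without young pair 4) to 25.14 between stages, -17.67 (without young pair 4) to 46.33 in young and -12.33 (without old pair 4) to 22.67 in old donors. The share at gene ends differed by -5.886 (without old pre 4) to 5.507 points between ages before transplantation, 3.598 to 9.130 (without old post 3, exact p = 0.0286) after it and -11.02 to -6.219 (without young pair 4) between stages. Similarity by age was 0.08100 to 0.1548 before and 0.08690 (without young post 3) to 0.1533 after transplantation, and by stage 0.06040 (without old pre 2) to 0.1174 (exact p at most 0.0156).

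The paired tests of peak number and gene-end share between stages missed the threshold without any young pair, old pair 3 or old pair 4, where 7 pairs remain (exact p = 0.0625 to 0.0938). Lists past the threshold were 1 to 3 between ages before transplantation (1 without young pre 1, 2 or 3, old pre 1 or 2, or any young post library), 0 to 2 after it (2 without young post 1 or old post 4), 1 to 3 in young (1 without young pre 1 or 2 or young post 2 or 3), 1 to 4 in old donors (1 without old pre 1, 2 or 3 or young post 3, 4 without old post 1), 1 to 8 between stages over both ages (1 without young pre 4, old pre 1 or 2, 8 without old post 1, 4 without old post 2), 1 (without old pre 1) to 4 (without old pre 3) between ages over both stages and 0 to 1 (without young pre 4) for the interaction.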

Other observations

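All tests in this part were chosen after the results they address were seen. Among the 66 regions that were higher before than after transplantation in young donors, 15 lay at 10 genes picked after the values were seen: the splicing factor genes Srsf3, Srsf7, Sfpq and Rbm39, the kinase genes Clk1 and Cdk11b, the cyclin gene Ccnl1, the nucleolin gene Ncl and the RNA-binding protein genes Celf2 and Rbfox1. These 15 regions were called 45 of 60 possible times in young pre libraries, 7 in old pre, 4 in young post and 3 in old post. Another 6 regions lay at Nfkbiz, Socs3, Dusp5 and Csrnp1, and were called 18 of 24 possible times in young pre, 1 in old pre, 1 in young post and 1 in old post. Because the sets were taken from the called regions, these counts describe them and test nothing, and no enrichment was tested. The count of 66 was 4 in the paired test, 6 without young pre 1, 2 without young pre 2 or young pre 3, and 0 with equal-length lists.

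A scan of 100-kb windows placed the 2 with the lowest post minus pre scores, adjusted for list length, among 273 windows next to each other on chromosome 8, between Gas8 and Rhou. Only protein-coding genes were used for naming, so genes of other types and repeats there were not looked at. The stretch spans 90.9 kb (123538487 to 123629382) and holds 27 regions, 10 of them called in pre libraries alone. Of the 27, a mean of 17.5 were called in young pre, 9.0 in old pre, 15.0 in young post and 8.5 in old post libraries. Its mean score was 30.3 ± 23.8 points (SD, n = 4) in young pre, -5.71 ± 12.0 in old pre, -12.8 ± 3.10 in young post and -11.8 ± 3.57 in old post, and it was lower after transplantation in 7 of 8 pairs, by 24.6 points on average, which follows from how it was chosen and tests nothing. Whole chromosomes, windows of 1 Mb and bins of the X chromosome were also looked at.

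A copy number gain in the young donors might raise calls along such a stretch and would persist in their transplanted cells. The young minus old difference was 36.0 points before transplantation (exact p = 0.0571) and -0.9842 after it (exact p = 0.714), but the stretch was chosen for low values after transplantation, so a gain cannot be told apart by it. A second hypothesis is that the stretch varies together with immediate early genes between samples. After centring each age, Pearson's r with the AP-1 list score over the 8 pre libraries was 0.952 (exact permutation within ages, p = 0.0052, adjusted p = 0.200 over 46 relations), so the relation cannot be told apart from chance. Without centring, r was 0.974 (exact permutation p = 9.9e-05, adjusted p = 0.0046) and Spearman's rho 0.976 (exact permutation p = 4.0e-04), and r was 0.921 without the 2 libraries farthest from the median. TGF-beta and BMP genes also passed (r = 0.891, exact permutation adjusted p = 0.0057), and after transplantation r with AP-1 genes was 0.00276.

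Regions of the imprinted genes Peg3 and Dlk1 were called in 6 and 5 of 8 pre libraries, respectively, and in no post library, which may reflect a change shared by imprinted genes. Over the whole list of imprinted genes, these 2 included, the difference was -10.3 points. Without Peg3 and Dlk1, which prompted the test, it was -2.365 points (exact p = 0.148), which leaves the hypothesis open.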
